A study of Mus musculus with 4 samples.

How the data were processed

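RNA was measured in 4 libraries of CJ9 mouse embryonic stem cells (strain 129S4/SvJae), 2 harvested at day 4 and 2 at day 6 of LIF withdrawal, all labelled wild type and titled as carrying Cas9 only. Groups and replicate numbers were taken from the sample titles, which match the labels' time and harvest entries. The culture protocol text in the labels gives 2 days without LIF for day 4 replicate 1, 4 days for day 6 replicate 1 and 6 days for day 4 replicate 2, and so disagrees with the titles for 3 of the 4 libraries. Nothing in the labels says that the 2 libraries of a day came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Other samples of the series, including cells with the locus deleted, were not analysed here.

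Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was isolated on oligo(dT) beads, and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, CASAVA and TopHat2 version 2.0.11 were used with the mouse genome build mm10. The quantifier, its version, the annotation release, whether strand was used, and any correction for GC content or multiply mapped reads are not given in the sources used here. Each library has 1 table of 35656 transcript rows, in the layout of an isoform tracking table, with RefSeq, UCSC and Ensembl transcript IDs and coordinates. The values are FPKM, fragments per kilobase of transcript per 1000000 mapped fragments, as the authors deposited them, with a lower and an upper FPKM bound per row and a status. A coverage column, deposited by the authors beside FPKM, holds the mean read depth over each transcript as an unscaled signal and was used only to describe depth. In each library 291 rows carry a low-data status, and 4 rows of day 4 replicate 2 carry a failed status.

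The tables hold no counts. Depth was estimated from the width of the deposited intervals, taking the interval as 2 Poisson standard deviations on each side, which gave about 3860000 and 3690000 mapped fragments for day 4 replicates 1 and 2 and 6600000 and 5880000 for day 6 replicates 1 and 2. The median ratio of coverage to FPKM was 0.698, 0.929, 1.82 and 1.59 in the same order, which also places the day 6 libraries above the day 4 libraries. The precision of low genes is therefore poorer at day 4, and the deposited intervals cover counting error only. Genes at 1 FPKM or more numbered 11206, 9449, 11840 and 11705. The 10 most abundant rows held 11.5, 19.8, 10.4 and 11.8% of the FPKM sum.

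Gene symbols were assigned by transcript ID from an NCBI RefSeq gene table of assembly GRCm38.p6 (30290 rows), from the RefSeq links of GENCODE M21 (160 rows) and from GENCODE M21 transcripts (3585 rows), both on the build that mm10 stands for. In all 95.5% of rows were named, and 1621 rows, 1264 of them UCSC IDs, kept their ID. FPKM of rows with the same symbol were summed. Tests ran on log2(FPKM + 1), with a pseudocount of 1 FPKM, over 11716 genes with a mean of at least 1 FPKM in the 4 libraries. A log2 difference on this scale understates the change of low genes. Day 6 was compared with day 4 with limma version 3.58.1 in R version 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no replicate block. Numbers 1 and 2 are shared between the days, but no label ties them to a shared culture, day or batch.

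Before the data were examined, 38 gene lists of pluripotency, germ layer, signalling, cell type, cell cycle, stress and technical genes were fixed, together with the tests, the alternatives and the rule for named genes. The 559 list entries came to 544 after entries without a matching row were left out and synonyms of the same gene were merged, and 36 lists had at least 5 tested members. Lists were tested with limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. Camera sets the members of a list against all other genes tested. The median log2 difference of all genes was 0.51, so a list called lower need not have fallen below 0. Camera with an estimated correlation and fry were run beside it. Both called 0 lists. A list is described by its median log2 difference and by members whose 2 days do not overlap, a pattern that chance gives to 33.3% of genes in the 2 directions together. Of all genes tested, 41.6% were higher and 11.5% lower at day 6 without overlap. The named genes are Evx1 and Evx1os, the 10 genes with the largest rise and the 10 with the largest fall among genes that pass and whose days do not overlap (filled up with genes that do not pass where fewer than 10 do, which was every one), 16 anchor genes, and up to 4 members of each list with the smallest p. Genes shown only to compare the day 4 libraries were chosen after their values were seen. For Evx1 and Evx1os an exact two-sided permutation test was run as well.

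The limma step was tested on simulated data: 200 of the 11716 genes, drawn from those with a mean log2(FPKM + 1) of at least 4, were changed 4-, 16- or 64-fold with the spread measured in each day, and 62.7, 94.0 and 98.5% of them lay under an unadjusted p of 0.05, but 0% passed the adjusted threshold. Unchanged genes lay under an unadjusted p of 0.05 in 7.95% of cases, so unadjusted counts run somewhat above the nominal rate. With the day 6 spread in both days, 100% of the changed genes passed the adjusted threshold.

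Alternatives chosen with the tests were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, TMM and median-of-ratios factors, quantile normalization, rescaling to a sum of 1000000, no trend, a robust fit, the replicate number as a block, an adjusted p of 0.1, a 2-fold minimum, the most abundant row per symbol in place of the sum, and leaving out each library in turn. After the data were seen, a correction for GC content was added, alone and with the block: in each library a loess curve (span 0.3) of the deviation from the gene means on the GC content of the GENCODE M21 transcript was subtracted, and 97.4% of tested genes had a GC value. Random lists matched on level and GC were drawn 10000 times. Parsing and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.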

Results

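The series concerns Evx1, a homeobox transcription factor gene of the primitive streak, and its antisense transcript, called Evx1as in the study and Evx1os in the annotation, in mouse embryonic stem cells that differentiate after the cytokine LIF is withdrawn. The 4 libraries analysed here all came from wild-type CJ9 embryonic stem cells (strain 129S4/SvJae) that carry Cas9 only. By their titles, 2 libraries were harvested at day 4 and 2 at day 6 of LIF withdrawal. The culture protocol text in the labels gives other days for some of them. Cells in which the locus was deleted were not analysed here, so the comparison available is day 6 against day 4 in cells with an intact locus. Each library was a stranded poly(A) RNA-seq library, given as 1 FPKM value per transcript. The widths of the deposited confidence intervals correspond to about 3860000 and 3690000 mapped fragments in day 4 replicates 1 and 2. For day 6 replicates 1 and 2 they correspond to about 6600000 and 5880000.

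Evx1 was measured first, because the study is about this locus. Its transcript (NM_007966) lies on the plus strand of chromosome 6, positions 52313498 to 52318378 of mm10. The files gave 12.1 FPKM (deposited interval 10.2 to 14.1) in day 4 replicate 1 and 133 FPKM (126 to 141) in day 4 replicate 2. The Evx1 transcript has 61.2% GC, and genes of 58 to 62% GC had a median 1.28 log2 units higher in day 4 replicate 2 than in replicate 1. How much of the gap between the day 4 libraries goes with GC was not tested for this gene. Both day 6 libraries were below both day 4 libraries, at 4.88 and 4.91 FPKM. The antisense transcript Evx1os (NR_038163), on the minus strand at positions 52308389 to 52314832, overlaps the 5′ end of Evx1. It was lower throughout, at 3.54 and 3.16 FPKM at day 4 and 1.204 and 2.04 FPKM at day 6. The log2 difference of day 6 minus day 4 was -2.83 with a standard error of 1.21 for Evx1 (limma, adjusted p = 0.362). It was -0.75 with a standard error of 0.41 for Evx1os (limma, adjusted p = 0.436). Neither passed. An exact two-sided permutation test of the 4 values gave p = 0.333 for each gene, the smallest p that 2 libraries against 2 can give. The size of the Evx1 difference rested on which day 4 library was used: it was -4.51 without day 4 replicate 1 (adjusted p = 0.000158) and -1.16 without day 4 replicate 2 (adjusted p = 0.00872). The remaining day 4 library is then assumed to vary as the day 6 libraries do. Whether the authors' quantification used strand is not given in the sources used here, so part of the signal over the shared stretch of Evx1 and Evx1os cannot be assigned to 1 of them.

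Lists of primitive streak and epiblast genes were called lower at day 6, and lists of blood and endothelial, fibroblast, extraembryonic endoderm and Hox genes were called higher. These calls were made with a preset correlation, and 0 of the 36 lists tested were called with an estimated correlation (smallest adjusted p = 0.547). Each call sets a list against all other genes tested, and the median log2 difference of all genes was 0.51. T (Brachyury), which marks the primitive streak and nascent mesoderm, measured 192 ± 85.2 FPKM at day 4 and 10.7 ± 0.409 FPKM at day 6 (SD, n = 2). Pou5f1 (Oct4), a core pluripotency factor, measured 372 ± 6.00 and 48.4 ± 9.10 FPKM. Igf2, an imprinted growth factor gene, measured 105 ± 59.0 FPKM at day 4 and 2863 ± 506 FPKM at day 6. The embryonic globin genes Hba-x and Hbb-bh1 were listed at 0 in both day 4 libraries, whereas Hba-x was given as 107 and 456 FPKM and Hbb-bh1 as 71.3 and 254 FPKM in day 6 replicates 1 and 2. No gene passed the adjusted threshold on its own (0 of 11716 tested with limma, 1793 at an unadjusted p under 0.05), and the statements on groups rest on tests of gene lists.

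**Figure D1:**
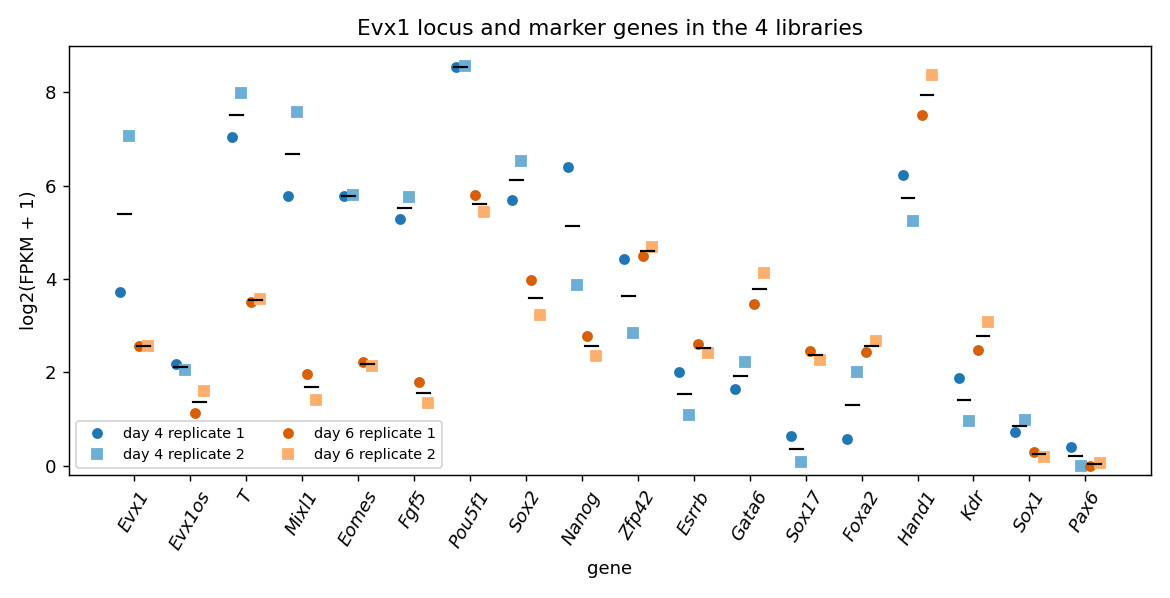
Expression of Evx1, Evx1os and 16 marker genes in the 4 libraries, with the gene on the x axis and log2(FPKM + 1) on the y axis; each symbol is 1 library (blue, day 4; orange, day 6) and each black line is the mean of a day's 2 libraries. T, Mixl1, Eomes, Fgf5, Pou5f1 and Sox2 lie lower in both day 6 libraries than in both day 4 libraries, Gata6, Sox17 and Hand1 lie higher, and Evx1 differs widely between the 2 day 4 libraries, at 12.1 and 133 FPKM.

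The primitive streak list was called lower at day 6 (camera with a preset correlation, adjusted p = 2.64e-11; adjusted p = 0.547 with an estimated correlation). Of its 17 tested members, 12 were lower in both day 6 libraries than in both day 4 libraries and 1, Amot, was higher, and the median log2 difference was -2.07. Of all genes tested, 11.5% were lower at day 6 without overlap. Mixl1, a streak homeobox gene, measured 122 ± 95.8 FPKM at day 4 and 2.28 ± 0.853 FPKM at day 6, and Eomes, a T-box factor of the streak, 54.2 ± 1.09 and 3.54 ± 0.156 FPKM (SD, n = 2). Lhx1 measured 9.44 ± 2.22 and 1.48 ± 0.329 FPKM. None of the 17 passed over all genes tested, and 5 passed when adjusted over the list alone, 4 lower and 1 higher. The list holds Evx1 itself, Nodal, Cdx1 and Sp5, which also stand in other lists. Its median was 1.79 log2 units higher in day 4 replicate 2 than in day 4 replicate 1. The call was kept without any 1 of the 4 libraries, with adjusted p from 9.25e-14 to 0.000482.

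Lists of pluripotency and epiblast genes were also called lower. The formative and primed epiblast list (adjusted p = 2.51e-05) had 8 of 12 tested members lower without overlap and 4 higher, with a median of -1.43. The general pluripotency list (adjusted p = 8.23e-06) had 7 of 11 lower without overlap and a median of -1.12. Both had adjusted p = 0.547 with an estimated correlation. Fgf5, a growth factor of the primed epiblast, measured 45.2 ± 10.5 FPKM at day 4 and 2.00 ± 0.637 FPKM at day 6 (SD, n = 2). Zic2 measured 55.1 ± 20.6 and 3.73 ± 0.405 FPKM, Dnmt3l, a cofactor of the de novo DNA methyltransferases, 42.5 ± 5.93 and 7.59 ± 1.31 FPKM, and Sox2 71.1 ± 28.9 and 11.6 ± 4.59 FPKM. Adjusted over the list alone, 4 epiblast genes and 1 general pluripotency gene passed, all lower, and none passed over all genes tested. The naive pluripotency list was not called (adjusted p = 0.702, 12 tested members). Its median of 0.62 had the opposite sign to the direction of its test, which was lower. Within it, Nanog was given as 83.8 and 13.7 FPKM at day 4 and 5.87 and 4.08 FPKM at day 6, whereas Zfp42 (Rex1) was given as 20.6 and 6.15 FPKM at day 4 and 21.4 and 24.9 FPKM at day 6. The median of day 4 replicate 2 minus day 4 replicate 1 was -1.53 for this list.

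Target genes of 3 signalling pathways were called lower with these lists, each with adjusted p = 0.547 with an estimated correlation. FGF/ERK targets (adjusted p = 9.53e-06) had 8 of 12 tested members lower without overlap and 2 higher, with a median of -1.26. Spry4, a feedback inhibitor of the pathway, measured 10.7 ± 2.52 FPKM at day 4 and 1.81 ± 0.206 FPKM at day 6 (SD, n = 2). Nodal targets (adjusted p = 0.000123) had 5 of 9 lower without overlap and 1 higher and a median of -0.90. Lefty2, a Nodal antagonist, measured 14.2 ± 5.27 and 2.51 ± 0.586 FPKM. Wnt targets (adjusted p = 0.000174) had 6 of 11 lower without overlap and 1 higher and a median of -1.18. Ccnd1 (cyclin D1) measured 73.8 ± 0.357 and 15.3 ± 1.04 FPKM and Axin2, a feedback inhibitor, 41.6 ± 23.9 and 9.15 ± 1.47 FPKM. No member of these lists passed, either over all genes tested or adjusted over the list alone. The Wnt and FGF/ERK lists lay 1.04 and 1.00 log2 units higher in day 4 replicate 2 than in day 4 replicate 1. The Wnt call ended without day 4 replicate 2 (adjusted p = 0.0756).

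Neuroectoderm and retinoic acid target lists were called lower than the other genes tested, with smaller differences. Neither median lay below 0 by more than 2 standard errors of the members (0.63 and 0.58). The neuroectoderm list (adjusted p = 0.0252; adjusted p = 0.547 with an estimated correlation) had 6 tested members and a median of -0.38, with Nes (nestin, an intermediate filament of neural progenitors) at 114 ± 37.2 FPKM at day 4 and 10.03 ± 6.04 FPKM at day 6 (SD, n = 2). Adjusted over the list alone, 1 member passed, and none over all genes tested. The retinoic acid list (adjusted p = 0.0352; adjusted p = 0.547 with an estimated correlation) had 8 tested members, 4 higher and 4 lower, and a median of -0.32. Cyp26a1, which degrades retinoic acid, measured 16.6 ± 6.69 and 2.61 ± 0.781 FPKM and Hoxb1 5.12 ± 1.11 and 0.378 ± 0.281 FPKM. These 2 passed when adjusted over the list alone. Of the 8 members, 3 were lower and 3 higher without overlap. Crabp2, among the higher ones, measured 5.65 ± 7.99 FPKM at day 4 and 18.0 ± 0.721 FPKM at day 6. The neuroectoderm call ended without day 4 replicate 1 (adjusted p = 0.101), day 4 replicate 2 (0.264) or day 6 replicate 2 (0.0716), and the retinoic acid call without the same libraries (0.262, 0.250 and 0.0520). Under a correction for GC content both calls ended as well (adjusted p = 0.0950 and 0.0576). The list medians were then -0.50 and -0.76, and the median of all genes went from 0.51 to 0.03.

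Of all genes tested, 41.6% were higher at day 6 without overlap, which is the share to set beside the counts of the lists called higher. Among the lists called higher, that of primitive, visceral and parietal endoderm had 11 of 13 tested members higher without overlap and a median of 1.87 (adjusted p = 0.000100; adjusted p = 0.547 with an estimated correlation). Its members include basement membrane genes that other cell types express as well. Col4a2, a basement membrane collagen, measured 23.9 ± 11.6 FPKM at day 4 and 128 ± 27.8 FPKM at day 6 (SD, n = 2), Plat 0.166 ± 0.00155 and 8.88 ± 3.92 FPKM, and Gata6, an endoderm transcription factor, 2.89 ± 1.08 and 13.2 ± 4.43 FPKM. Ttr, the thyroxine carrier transthyretin, was listed at 0 in both day 4 libraries and at 8.13 and 11.04 FPKM at day 6. Adjusted over the list alone, 9 of the 13 passed, all higher, and none over all genes tested. The call ended without day 4 replicate 1 (adjusted p = 0.0797). The definitive endoderm list, with 7 tested members, was not called (adjusted p = 0.697).

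The imprinted gene list was called higher, with 13 of 18 tested members higher without overlap and 1, Snrpn, lower, and a median of 1.71 (adjusted p = 0.00149; adjusted p = 0.547 with an estimated correlation). Mest measured 17.7 ± 8.15 FPKM at day 4 and 320 ± 35.6 FPKM at day 6, Igf2r, the receptor that clears Igf2, 9.33 ± 4.49 and 87.8 ± 16.7 FPKM, and Dlk1, a Notch-related ligand, 4.87 ± 2.71 and 49.2 ± 32.5 FPKM (SD, n = 2). Igf2, Mest and Igf2r were among the members with the smallest p, and 3 members passed when adjusted over the list alone, against none over all genes tested. The median of day 4 replicate 2 minus day 4 replicate 1 was -0.80. The call ended without day 4 replicate 2 (adjusted p = 0.0512).

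Mesoderm and cardiac, mesenchymal transition, blood and endothelial, and fibroblast lists were called higher too. The mesoderm and cardiac list (adjusted p = 0.0108) had 10 of 14 tested members higher without overlap and 1 lower, with a median of 1.92. The mesenchymal transition list (adjusted p = 0.0102) had 10 of 14 higher without overlap and a median of 1.52. The 2 lists share Snai2 and Twist1, and each had adjusted p = 0.547 with an estimated correlation. Hand1 and Hand2, transcription factors of the heart and extraembryonic mesoderm, measured 55.2 ± 26.3 and 1.32 ± 0.389 FPKM at day 4 and 255 ± 105 and 32.1 ± 22.3 FPKM at day 6 (SD, n = 2). Fn1 (fibronectin) measured 160 ± 29.7 and 653 ± 36.1 FPKM. Adjusted over the list alone, 7 mesoderm and 6 mesenchymal members passed, all higher, and none over all genes tested. The blood and endothelial list (adjusted p = 0.00432; adjusted p = 0.639 with an estimated correlation) had 12 of 14 tested members higher without overlap and 1 lower and a median of 1.38. In it, 3 members passed when adjusted over the list alone. Beside the globins, Kdr, an endothelial receptor, measured 1.82 ± 1.25 and 6.01 ± 1.99 FPKM. The list of fibroblast genes, fixed as a marker of feeder cells, moved with these groups (adjusted p = 0.0252; adjusted p = 0.547 with an estimated correlation), with 8 of 12 tested members higher without overlap and 1 lower, a median of 1.92 and 6 members passing when adjusted over the list alone. In it Col1a1, a fibrillar collagen, measured 5.93 ± 0.319 FPKM at day 4 and 92.6 ± 48.4 FPKM at day 6, Col3a1 0.928 ± 0.239 and 38.8 ± 6.73 FPKM. Postn was listed at 0 in both day 4 libraries and at 20.5 and 37.6 FPKM at day 6. Without day 4 replicate 1 none of these 4 lists was called (adjusted p = 0.448, 0.688, 0.443 and 0.297 for the mesoderm, mesenchymal, blood and fibroblast lists). Without day 4 replicate 2 the blood and fibroblast calls ended as well (0.0890 and 0.208).

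Hox genes and trophoblast genes were also called higher, where 41.6% of all genes tested were higher without overlap. Of 15 tested Hox genes, 11 were higher without overlap and 2 lower, with a median of 1.21 (adjusted p = 0.0229; adjusted p = 0.639 with an estimated correlation). Hoxc10, a posterior member, measured 0.169 ± 0.0810 FPKM at day 4 and 7.05 ± 0.971 FPKM at day 6 (SD, n = 2), and Hoxb6 was listed at 0 in both day 4 libraries and at 4.66 and 5.83 FPKM at day 6, whereas Hoxb1, at the anterior end of its cluster, was higher at day 4. Adjusted over the list alone, 8 passed higher and 1 lower, and none over all genes tested. The trophoblast list (adjusted p = 0.0343; adjusted p = 0.718 with an estimated correlation) had 6 of 10 tested members higher without overlap and a median of 1.59. Krt7 measured 41.9 ± 22.9 and 138 ± 11.8 FPKM. Plac1, the 1 member that passed when adjusted over the list alone, was listed at 0 at day 4 and at 30.2 and 45.7 FPKM at day 6. Both calls ended without day 4 replicate 1 (adjusted p = 0.782 for each), and the Hox call also ended without day 4 replicate 2 (0.0512) and under a correction for GC content (0.0696). Measured from the median of all genes, the list's median was 0.70 before that correction and 0.73 after it.

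**Figure D2:**
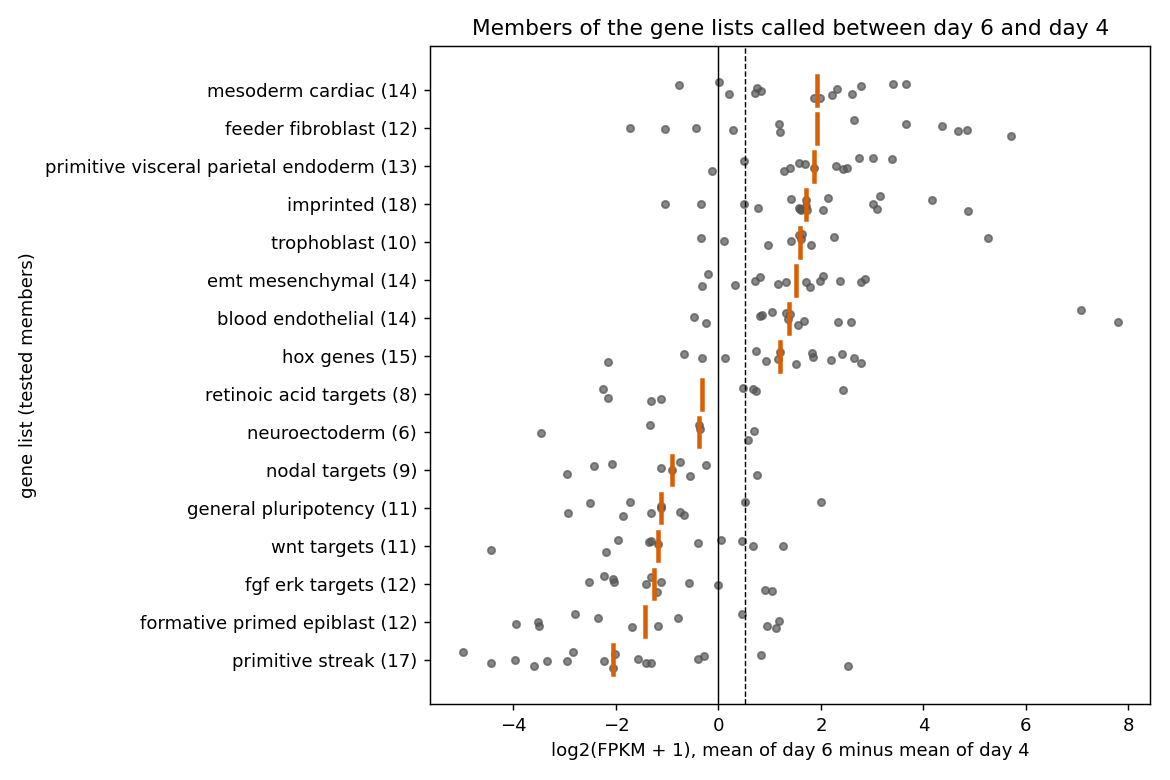
Log2 difference in FPKM + 1 (mean of day 6 minus mean of day 4, x axis) of the tested members of the 16 gene lists called between the days (y axis, with the number of tested members); each grey point is 1 gene, each orange bar the list's median, the solid line 0 and the dashed line the median of all genes tested, 0.51. The primitive streak list has the lowest median, -2.07, and the mesoderm and cardiac list the highest, 1.92, with members on both sides of 0 in most lists.

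The genes with the largest differences without overlap, none of which passed, belong partly to these groups and partly to others. On the side lower at day 6, Nefl, a neurofilament subunit, measured 540 ± 32.6 FPKM at day 4 and 8.32 ± 7.45 FPKM at day 6, Foxi3, a forkhead factor, 81.9 ± 60.03 and 1.34 ± 0.273 FPKM, and Trim67 25.3 ± 10.99 and 0.716 ± 0.336 FPKM (SD, n = 2). Halr1 was given as 9.78 and 24.7 FPKM at day 4 and listed at 0 in both day 6 libraries. Nefm, another neurofilament subunit, was given as 273 and 38.3 FPKM at day 4 and 4.23 and 2.51 FPKM at day 6. Sp5, a Wnt-responsive factor, was given as 59.1 and 734 FPKM and 10.5 and 7.24 FPKM. On the side higher at day 6, Spink1 was listed at 0 in both day 4 libraries and at 34.9 and 31.4 FPKM at day 6, as was a transcript without a gene name (uc009iyh.1, mm10 chromosome 7, 105558156 to 105558388), at 40.3 and 39.6 FPKM. Acta2, smooth muscle actin, was given as 13.4 and 0.410 FPKM at day 4 and 250 and 222 FPKM at day 6. Hba-a1, Rpl34-ps1, Rps27rt, Cryab and Gm5643 complete the 20 genes, and their values are uncertain, since each either has near-identical copies or was far apart between the 2 day 4 libraries (Cryab was listed at 71.3 and 0 FPKM at day 4).

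Tested gene by gene with limma on log2(FPKM + 1), 0 of 11716 genes passed an adjusted p of 0.05 (smallest adjusted p = 0.267). At the same time 1793 genes lay under an unadjusted p of 0.05, 1511 higher and 282 lower at day 6, where the nominal rate gives 586. The latter count was 8278 without day 4 replicate 1, 6933 without day 4 replicate 2, 283 without day 6 replicate 1 and 257 without day 6 replicate 2. Past the adjusted threshold were 7837 genes without day 4 replicate 1 and 6081 without day 4 replicate 2, where the remaining day 4 library is assumed to vary as the day 6 libraries do, and 0 without either day 6 library. The split into higher and lower genes at an unadjusted p under 0.05 differed between scales and filters. The median log2 difference of all genes was 0.51 on the deposited scale, and the counts were 769 higher and 566 lower with TMM factors (median 0.12), 721 and 596 with median-of-ratios factors (0.08), and 644 and 797 after quantile normalization (-0.02). They were 2428 and 419 without a filter (0.23) and 1067 and 1066 with the GC correction (0.03). The 2 days did not overlap for 4869 genes higher and 1347 genes lower at day 6, which is 41.6 and 11.5% of genes tested and together 53.1% against 33.3% by chance, and 739 and 114 of these differed at least 4-fold. The 2 day 6 libraries correlated at Pearson r = 0.981 across genes, which are not independent replicates, and the SD of their log2 difference was 0.36. The day 4 libraries correlated at r = 0.671 with an SD of 1.69, and each was closer to both day 6 libraries (r = 0.828 and 0.818 for replicate 1, 0.731 and 0.709 for replicate 2) than to the other. In data simulated with the measured spread of each day, 0% of genes changed 4-, 16- or 64-fold passed the adjusted threshold, and with the day 6 spread in both days 100% did. With the measured spread, 7.95% of unchanged genes lay under an unadjusted p of 0.05, which is above the nominal rate behind the 586.

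The day 4 libraries differed from each other in genes that most cells express. B2m, a component of MHC class I, was given as 49.3 FPKM in day 4 replicate 1, listed at 0 in day 4 replicate 2, and given as 142 and 145 FPKM at day 6. Eef1a1, a translation factor, was given as 2278, 52.6, 3658 and 4190 FPKM in the same order. Of 4135 genes at 10 FPKM or more in the other 3 libraries, 114 were listed at 0 in day 4 replicate 2, against 2 of 3518 for day 4 replicate 1 and 0 for each day 6 library. The difference between the day 4 libraries followed the GC content of the transcripts: replicate 2 minus replicate 1 had a median of -1.89 among 93 genes of 34 to 38% GC and of 1.68 among 245 genes of 62 to 66% GC. Transcripts of the mitochondrial chromosome held 4.76% of the FPKM sum in day 4 replicate 1, 0.0690% in day 4 replicate 2, and 0.670% and 0.762% at day 6. Because genes that cells commonly need were listed at 0 in 1 library, a value of 0 is reported here only as listed at 0.

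**Figure D3:**
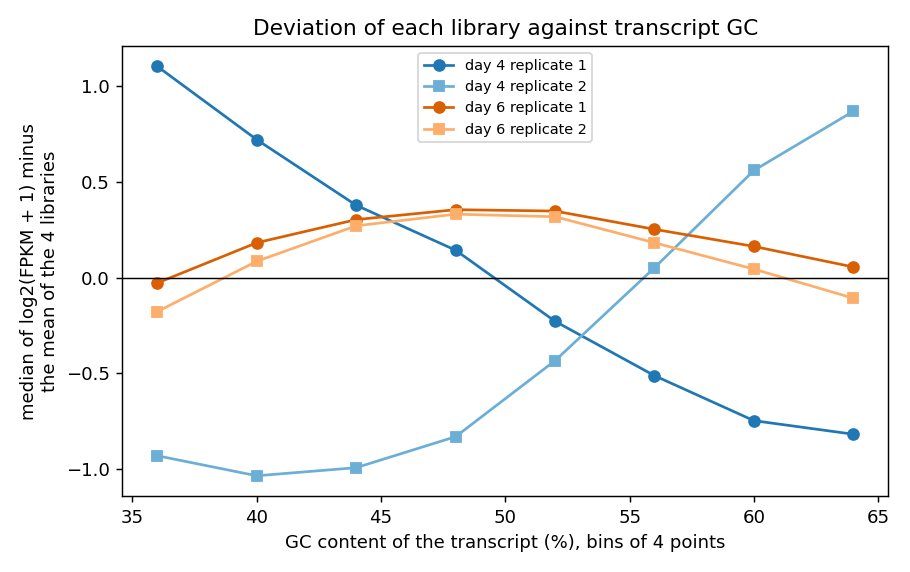
Median deviation of each library from the mean of the 4 libraries, in log2(FPKM + 1) (y axis), in bins of transcript GC content (x axis, %); each line is 1 library. Day 4 replicate 1 goes from 1.10 at 34 to 38% GC to -0.82 at 62 to 66%, day 4 replicate 2 from -0.93 to 0.87 over the same bins, and both day 6 libraries stay between -0.18 and 0.36.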

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

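The GC correction, alone and with the block, was chosen only after the results were seen; the others were chosen in advance. The count of genes past an adjusted p of 0.05 stayed at 0 (limma) with every alternative tried except the replicate block and the removal of a day 4 library. Leaving out each library in turn gave from 0 to 7837 genes, 0 to 5847 higher and 0 to 1990 lower at day 6: 7837 without day 4 replicate 1, 6081 without day 4 replicate 2, and 0 without either day 6 library. The rise has its cause in the construction, since 1 day 4 library is left and its group is assumed to vary as the day 6 libraries do, so these counts say little about the days. At an unadjusted p under 0.05 the same removals gave from 257 to 8278 genes against 1793, 241 to 6123 higher and 16 to 2155 lower.

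The numbers 1 and 2 were treated as names, since the deviations of same-numbered libraries correlated at -0.09 across genes and no label pairs them. With the replicate number as a block, 67 genes passed, 54 higher and 13 lower, and 18 lists were called. With the GC correction and the block together, 0 genes passed, and 855 higher and 773 lower lay under an unadjusted p of 0.05.

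Counts at an unadjusted p under 0.05 moved with the filter, to 2847 genes without one (2428 higher) and 1027 at a mean of 5 FPKM (840 higher and 187 lower), where the number of genes tested differs. They moved with the scale too, to 769 higher and 566 lower with TMM factors, 721 and 596 with median-of-ratios factors, and 644 and 797 after quantile normalization. With the GC correction they were 1067 and 1066. The cause was not tested.

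Of the 16 lists called, 0 were called with an estimated correlation and 0 with fry, and 13 remained with the GC correction and the preset correlation. Leaving out each library gave from 9 to 19 lists: without day 4 replicate 1, 9 lists of which 7 were among the 16; without day 4 replicate 2, 10 and 9; without day 6 replicate 1, 19 and 16; without day 6 replicate 2, 16 and 14. Retinoic acid targets also lost the call without a filter (adjusted p = 0.289) and with TMM (0.0740) and median-of-ratios factors (0.0787), the neuroectoderm list with median-of-ratios factors (0.0509) and Hox genes after quantile normalization (0.0890). The primitive streak, general pluripotency, formative epiblast, FGF/ERK and Nodal lists were called with the preset correlation in every alternative fit run for lists, which did not include the most abundant row per symbol. The Evx1 difference ranged from -4.51 to -1.16 when libraries were left out, past the threshold at both ends, and did not pass in any other alternative run for it.

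Of 157 named genes with a test, none of which was called, 12 changed sign in at least 1 alternative, and the cause was not tested. Cldn4 (0.35 as deposited) was -0.14 with TMM, -0.19 with median-of-ratios and -0.029 with either GC correction, and Rhox5 (0.24) was -0.19, -0.23 and -0.30, and -0.41 after quantile normalization. Quantile normalization also gave Ncam1 -0.12, Tdrd1 -0.30, Jazf1 -0.35 and Trib3 -0.028. Either GC correction gave Tdrd1 -0.12, Jazf1 -0.11 and Mdm2 -0.0039. When libraries were left out in turn, Cldn4 ranged from -0.56 to 1.27, Rhox5 from -0.46 to 0.94, Ddx4 from -1.15 to 0.60, Usp17la from -2.44 to 0.029, Trib3 from -0.13 to 1.56, Tdrd1 from -0.049 to 1.17, Nrarp from -1.97 to 0.80, Junb from -2.78 to 0.56 and Tubb3 from -0.00113 to 1.16. Depth limits the genes near 1 FPKM at day 4, where a transcript of 1 kilobase stands on about 4 fragments.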

Other observations

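The tests of the day 4 spread by fragment number and by the streak list as a sign of a mislabelled library or of 6 days of culture, and those of the lists whose call ended with the GC correction and of depth by day 4 levels and by direction, were chosen only after the results were seen. Several gene groups that were not called held genes with large differences, none of which passed over all genes tested. In the glycolysis and hypoxia list (camera with a preset correlation, adjusted p = 0.121, median log2 difference 1.37), 10 of 18 tested members were higher at day 6 without overlap. Of all genes tested, 41.6% were, and chance gives 33.3% in the 2 directions together. In the same list 2 were lower. Ndrg1, a gene induced by hypoxia, measured 2.91 ± 2.06 FPKM at day 4 and 54.2 ± 13.2 FPKM at day 6. Slc2a1, a glucose transporter, measured 218 ± 45.1 and 841 ± 31.7 FPKM (SD, n = 2). In the cholesterol synthesis list (adjusted p = 0.531, median 0.80) Dhcr7, an enzyme of the pathway, measured 5.95 ± 2.30 and 27.6 ± 7.35 FPKM. Of cell cycle genes, Ccnb2 (cyclin B2) of the G2/M list (adjusted p = 0.741, median 0.68) measured 17.2 ± 1.499 and 64.4 ± 13.2 FPKM. Cdkn1c, an inhibitor of cyclin-dependent kinases that also stands in the imprinted list, measured 68.2 ± 22.7 and 280 ± 64.8 FPKM. The inhibitor list had adjusted p = 0.826 and a median of 0.78. The housekeeping list had adjusted p = 0.702 and a median of 1.03.

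Other lists that were not called had medians nearer to 0. Medians below 0 on every scale tried were those of p53 targets (adjusted p = 0.0923, median -0.17), immediate early and heat shock genes (0.125, -0.01), germ cell genes (0.176, -0.0021) and Notch targets (0.531, -0.09). The medians of polycomb and DNA methylation genes (0.0702, 0.20), LIF/STAT3 targets (0.106, 0.04), BMP targets (0.531, 0.12), genes next to Evx1 (0.531, 0.46), unfolded protein and amino acid stress genes (0.593, 0.20), replication-dependent histones (0.632, 0.47), definitive endoderm genes (0.697, 0.35), epithelial genes (0.741, 0.42), G1/S genes (0.994, 0.34) and ribosomal protein genes (0.994, 0.46) changed sign with TMM factors, median-of-ratios factors, quantile normalization or the GC correction, so no direction is given for them. For the polycomb, LIF/STAT3, BMP, Evx1 neighbour, stress, histone and ribosomal lists the test pointed lower while the median on the deposited scale was above 0. Hibadh, a neighbour of Evx1, measured 5.16 ± 3.57 FPKM at day 4 and 18.1 ± 3.17 FPKM at day 6 (SD, n = 2). The list of genes of the 2-cell-like state had 1 tested member and that of mitochondrially encoded genes had 0 matched members, so neither was tested.

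The 2 day 4 libraries differed across genes with an SD of 1.65 log2 units among genes with a GC value, against 0.350 for day 6. GC content may contribute, since a curve on transcript GC explained 37.1% of the variance of the difference, but it is not the whole cause, because the SD after its removal was 1.31, 3.74 times that of day 6. Shallow sequencing is not the whole cause either, since among 3118 genes with at least 200 implied fragments the SD was 1.96 at day 4 and 0.302 at day 6. A day 6 library under the name of day 4 replicate 2 was first tested with 17 genes. These were at 1 FPKM or less in day 4 replicate 1 and at 20 FPKM or more in both day 6 libraries. Of them 4 reached 10 FPKM (23.5%, exact 95% interval 6.81 to 49.9%), with 1 of 3 genes of the opposite kind at 5 FPKM, which decided nothing. A test chosen after that result placed the streak list 2.67 log2 units above the day 6 mean in that library. This was percentile 100 of 10000 random lists of like level and GC (95% of them from -0.63 to 0.77). The streak list had by then been seen to be lower at day 6 and higher in this library than in day 4 replicate 1. Housekeeping genes stood at percentile 0 of such lists between the day 4 libraries, so a list with no tie to cell state can stand out as far. The percentile therefore does not decide whether this is a day 6 library. Against day 6 replicate 2 alone, which every label puts at 6 days, the same median was 3.11 (percentile 100, random lists from -0.60 to 0.86). For the same reasons this does not decide on the 6 days that the protocol text gives day 4 replicate 2. The 2 days that the protocol text gives day 4 replicate 1 and the 4 days it gives day 6 replicate 1 were not tested and remain open. A mix-up with a library outside these 4 and RNA quality also remain open and were not tested.

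Primitive streak genes had a median 1.79 log2 units higher in day 4 replicate 2 than in day 4 replicate 1. GC content and level alone do not give this, since the median lay at percentile 99.93 of random lists matched on both, whose own median was 0.72. BMP targets lay 1.58 higher (percentile 99.99) and naive pluripotency genes at -1.53 (percentile 1.33). Housekeeping genes also stood at -3.23 (percentile 0), so a list with no tie to cell state stood out as well. Replication-dependent histones stood at 1.06 (percentile 99.57). LIF/STAT3 targets lay 1.59 higher (percentile 95.39) and general pluripotency genes at -0.37 (percentile 38.26). The histone gene H2ac13, picked after its values were seen, was given as 273 FPKM in day 4 replicate 1 and 11491 FPKM in day 4 replicate 2. A candidate explanation is that the cells of the 2 libraries were at different stages of differentiation, which 1 library each cannot separate from the quality of the libraries.

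Of the 16 lists called between the days, 13 were called in the same direction after the GC correction, with the preset correlation. None of the 16 was called after it with an estimated correlation (camera, smallest adjusted p = 0.455). As far as the preset correlation holds, the 13 calls did not depend on the GC trend that the correction removed. For the Hox, neuroectoderm and retinoic acid lists, whose medians went from 1.21 to 0.76, from -0.38 to -0.50 and from -0.32 to -0.76, the call ended with a smallest adjusted p of 0.0576. Measured from the median of all genes they went from 0.70 to 0.73, from -0.89 to -0.52 and from -0.83 to -0.79. The mean t statistic of the members minus that of other genes went from 1.91 to 1.27, from -2.07 to -1.91 and from -1.79 to -2.39. The SD of t over all genes went from 1.78 to 2.14. These shifts in lists of few members do not settle whether GC gave the calls, and GC and day cannot be told apart there. Lower depth at day 4 could lose low genes there, which raises their log2 differences and does not itself put a median below 0. Camera sets a list against all other genes, and the median of all genes was 0.51. A list could thus be called lower without a fall of its own. Of the 8 lists called lower, 6 had medians below 0 by more than 2 standard errors of their members (the neuroectoderm and retinoic acid lists did not). These lists were picked as lower from the same values, and the standard errors take genes as replicates. A part for depth in these calls is therefore not excluded. For the lists called higher depth stays open. A filter at a mean of 5 FPKM, with which 12 of the 16 lists were called, keeps genes that are low at day 4. With genes at 5 FPKM or more in both day 4 libraries, 4 of the 8 could be tested. Of these, 2 were called, extraembryonic endoderm (adjusted p = 0.00392) and imprinted genes (0.000220). Of the 3 splits of the 4 libraries into 2 and 2, the real one gave 1793 genes at an unadjusted p under 0.05 and 1 split gave as many, the real one itself, with 125 in the highest other, and 3 splits are too few for a share under 0.05. Of the 8 lists called higher, 7 lost the call without day 4 replicate 1 and 4 without day 4 replicate 2, the imprinted list among the latter, so 0 of the 8 kept it under both removals, and no biological cause was tested beyond the day itself.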
